A study of Mus musculus with 6 samples.

How the data were processed

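Mouse cortex at postnatal day 25 was lysed, ribosomes carrying an HA tag were immunoprecipitated with an anti-HA antibody on magnetic beads, and RNA was purified on silica columns, per the labels' protocols. Libraries were made with a stranded mRNA kit, per the labels' protocols, which selects polyadenylated RNA and keeps strand. There were 6 libraries in 2 groups, 3 Control and 3 Rheb cKO, assigned from the genotype label and title of each sample. The titles number the libraries of each group alike, but the values used here carry no library of their own.

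The submitters' processing notes name TopHat2 2.1.0, Cuffdiff 2.2.1 and the mouse genome build mm10, without role or settings. The release of the gene annotation, the strand setting and the scaling between libraries are not given in the sources used here. Per the file headers, the deposited FPKM values (fragments scaled to the length of the gene model and to the mapped fragments of the library) are 1 value per gene for Control and 1 for Rheb cKO, so the authors pooled the libraries of each group. The deposited log2 fold change is Rheb cKO over Control with no pseudocount; it differed from the log2 ratio of the FPKM columns by at most 1.23e-05. The authors' table also holds a test score per gene (the signed Cuffdiff statistic), a p-value and a q-value. These p-values come in steps of 5e-05, so the 410 genes at the smallest p-value share a q of 0.00161. Benjamini-Hochberg adjustment of the authors' p-values over the table gave their q-values to within 7.27e-05. There were 2 tables: the longer has 13192 genes, each with test status OK, and the shorter holds the 1150 genes of the longer that are called at a q under 0.05. One further line of the longer table is empty here and was not used. Genes without status OK were not analysed here. A column with no heading beside a few lactate transporter genes carries marks of the authors and was not used as data.

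The FPKM columns summed to 597927 in Control and 597646 in Rheb cKO over the listed genes, with medians of 8.52 and 8.66. Depth per library is unknown here, so no interval based on counts is given, and the precision of a value cannot be set by its reads. The authors' q-values are the measure of error behind each single gene, and no test across libraries could be run from pooled values. If the libraries of a group are not from separate animals, those q-values measure only the spread between these libraries.

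In 23 rows a gene symbol had been turned into a date by spreadsheet software; all 23 were restored through the gene ID. Of the gene IDs, 99.7% were found in GENCODE M21, an annotation of the same build as mm10, all on the same chromosome as in the authors' table; coordinates, strand, biotype, transcript length and GC were taken from it, and positions count from 1. A total of 12 genes were listed at 0 in Control (4 of them called) and 5 in Rheb cKO; these have no finite fold and were left out of lists and medians, which leaves 13175 genes. There were 8 symbols carried by 2 gene IDs each.

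Before the data were examined, the following were fixed: the q threshold of 0.05, 28 gene lists with 896 genes, the list tests, the rule for naming genes and a set of other settings. The rule named Rheb, Rhebl1 and Rpl22, the 10 most positive and the 10 most negative called genes with a mean FPKM of 1 or more, up to 3 called members of each list with the highest absolute fold (or the 2 most abundant members where no called member has a mean FPKM of 1 or more) and the 5 most abundant called genes. It gave 93 genes, of which 83 are called; some of them are not reported here. The lists are the pathway, cell type, sex and blood lists whose results are all given in the report, chosen from textbook knowledge and not from these libraries. Some lists share members, such as Vim (translation factors with a TOP motif and reactive astrocyte genes), Gfap, Aldoc and Enpp2.

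For each list, the median of the deposited log2 fold changes over its measured members was set against 10000 random lists of the same size, drawn from the same table and matched in 20 bins of mean FPKM. A list was past the threshold under percentile 2.5 or above percentile 97.5. Members called higher and called lower were each compared with all other tested genes by Fisher's exact test (2-sided), with Benjamini-Hochberg adjustment over the 56 tests. Counts adjusted over the list alone use Benjamini-Hochberg on the authors' p-values of the list's members. The pan-neuronal median was also compared with the pooled median of 5 non-neuronal lists against random pairs of lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

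The list code was tested on simulated folds for the comparison of Rheb cKO with Control over 13175 genes. Of 140 lists with no shift, 2.86% came out past the threshold, and 97.1% of lists shifted by 0.5 on the log2 scale did. A simulated adjustment step on the same genes, with 200 changed by known folds, called 4% of those changed by log2 0.5, 58% at log2 1, 98% at log2 2 and 100% at log2 3, with 6 unchanged genes called. The noise in that simulation was normal, with the spread of the folds of uncalled genes at the same expression, so these shares check the code and are not the power of the authors' test.

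The other settings were a q under 0.01 or 0.1, an added fold minimum of 1.5, adjustment over genes with a mean FPKM of 1 or more, folds relative to the median fold, the shorter table, log2 values with 1 or 0.1 added to each FPKM, lists limited to genes with a mean FPKM of 1 or more, and random lists not matched on expression. After the data had been seen, all folds were also corrected for transcript length and GC (a quadratic fit over 11452 protein-coding genes). Reduced forms of the translation factor list and of the sterol list were added then too. So were a count and the neuronal against non-neuronal difference without oligodendrocyte markers.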

Results

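The series asked what changes in the RNA bound to tagged ribosomes of mouse cortex when Rheb, a small GTPase that switches on the growth-controlling kinase complex mTORC1, is deleted. All 6 libraries came from cortex at postnatal day 25. RNA was taken from cortical lysate by immunoprecipitation with an anti-HA antibody, which pulls down ribosomes carrying an HA-tagged protein together with the mRNAs on them. The 3 Control libraries are titled with floxed Rheb alleles and the ribosome tag. The 3 Rheb conditional knockout (Rheb cKO) libraries carry Syn-Cre in addition, a name used for Cre recombinase under the neuronal synapsin promoter, and their genotype label calls them a Rheb knockdown. The titles name no Cre for the Control group, and whether its ribosomes carried the tag without one is not stated. Every fold, those of the synaptic, ribosomal, sterol and non-neuronal lists included, therefore compares these precipitates as labelled and is not assigned to the loss of Rheb alone. The labels do not say whether each library is a separate animal. Expression was available as 1 FPKM value per gene and group, pooled by the authors over the libraries of a group, so the spread between libraries and the depth of each library are unknown here and no SD is given.

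Rheb itself was lower in the group labelled as its knockout. In the authors' deposited table its FPKM was 22.7 in Control and 9.20 in Rheb cKO, a log2 fold change of -1.30 (q = 0.00161, Cuffdiff), which left 40.6% of the Control level. The gene lies on the minus strand of chromosome 5 from 24802823 to 24842624 in mm10. Its value covers the whole gene model, so transcripts from an allele that lost only part of the gene still count. Rhebl1, the closest relative of Rheb, had a log2 fold change of 0.23 (q = 0.671) in the authors' deposited table. Rpl22, which carries the HA tag in a widely used Cre-dependent ribosome-tag mouse, stood at 0.08 (q = 0.872) in the authors' deposited table.

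Among 13192 genes tested by Cuffdiff, 1150 were called at a q under 0.05, 8.72% of the total. Of these, 546 were higher and 604 lower in Rheb cKO. The changes were mostly moderate over the called genes with a finite fold, which leaves out 4 listed at 0 in Control. The median log2 fold change was 0.56 among genes called higher and -0.70 among genes called lower. In the same set, 86 genes at least doubled and 159 fell by at least 1 on the log2 scale. At an unadjusted p under 0.05 the same table holds 2798 genes. The calls depend on the threshold: at a q under 0.01 there were 256 higher and 365 lower. Over the 12018 genes with a mean FPKM of 1 or more the median log2 fold change was 0.03, so the 2 groups were centred alike. As each called gene rests on pooled group values, its direction could not be followed in single libraries.

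**Figure D1:**
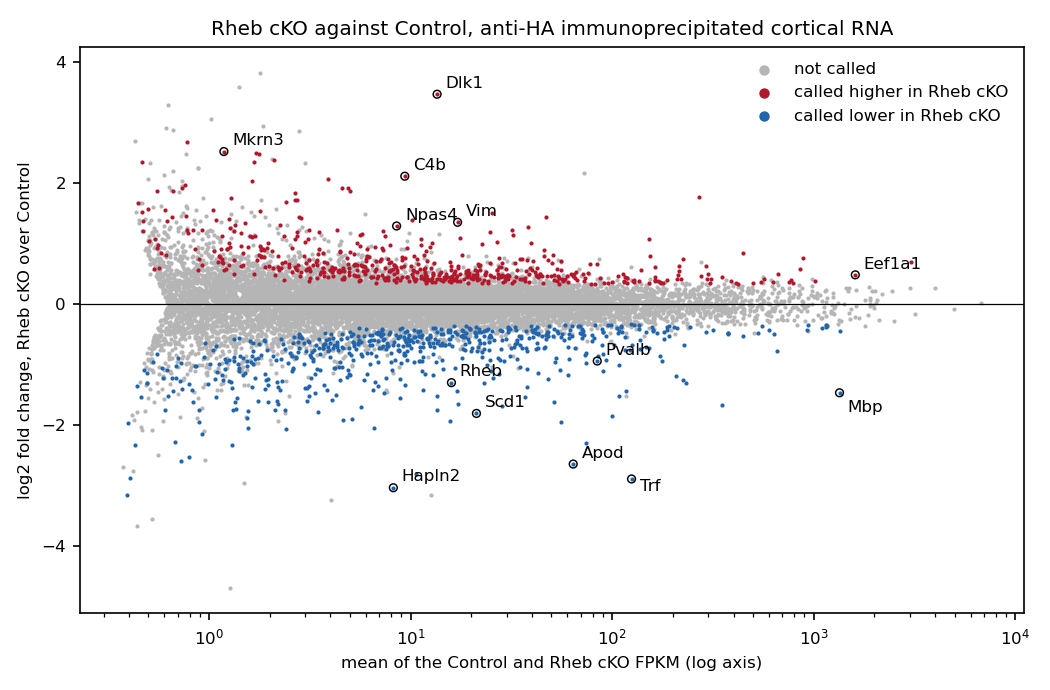
Log2 fold change of Rheb cKO over Control (y axis) against the mean FPKM of the groups (x axis, log scale), 1 point per gene with a finite fold in the authors' deposited table; red points are called higher (546 genes, less 4 listed at 0 in Control), blue points called lower (604), grey points not called. Circled genes are named in the text; Dlk1 at 3.47 and Hapln2 at -3.04 stand farthest from 0 among called genes with a mean FPKM of 1 or more.

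The clearest group change was a loss of transcripts of mature oligodendrocytes, the myelin-forming cells. Of 30 measured oligodendrocyte markers, 28 fell (30 when adjusted over the list alone) and all had a fold below 0. The median log2 fold change of the list was -1.45, under all 10000 random lists of matched expression, whose central range ran from -0.09 to 0.12. Members called lower were over-represented (Fisher's exact test, 2-sided, adjusted p = 4.00e-34). In the authors' deposited table Mbp, which encodes a main protein of myelin and was among the most abundant called genes, went from 1973 to 713.0 FPKM (log2 fold change -1.47, q = 0.00161). Trf, the iron carrier transferrin (-2.89), Ppp1r14a (-2.30) and Gjb1, a gap junction protein of myelinating cells (-2.05), fell further on the log2 scale in the authors' deposited table (q = 0.00161 each). The markers Evi2a (-1.46) and Bcas1 (-0.64) were the ones not called in the authors' deposited table. Here and in the other lists, members outside the rule for naming genes are given where 5 or fewer stand apart, and were chosen after their values were seen.

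Other cell types moved less and in different directions. Astrocyte markers had a median of -0.23 (percentile 0 among random lists), with 5 of 29 called lower, 2 higher, and 10 lower when adjusted over the list alone (Fisher's exact test for lower, adjusted p = 0.0608). Those lower in the authors' deposited table included the neurotensin receptor gene Ntsr2 (-0.86), S100b (-0.85) and Mfge8 (-0.82), each with q = 0.00161. Fgfr3 and Gfap, the filament protein of astrocytes, were the astrocyte markers called higher. Endothelial and mural markers had a median of -0.25 (percentile 0.13), and 5 of 20 fell (Fisher's exact test, adjusted p = 0.0162). This list pools both cell types, which were not tested apart, and 7 of its members had a fold above 0. With 1 added to each FPKM the median of the list was -0.15. The 5 were Kcnj8 (-1.29), Vtn (-1.08), Acta2 (-0.90), Myl9 and Rgs5 in the authors' deposited table. Oligodendrocyte precursor markers stayed within the random range (median -0.04, percentile 16.7). Olig1 (-0.95), which mature oligodendrocytes also express, and Gpr17 (-0.58) were the 2 of 16 that fell in the authors' deposited table.

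Microglia markers had a median of 0.27 over 17 genes (percentile 98.2), with 0 called by Cuffdiff in either direction and 4 higher at an unadjusted p under 0.05. Of the 17 markers, 9 had a fold above 0 and 8 below, at low median FPKM (1.91 in Control, 1.75 in Rheb cKO). The most abundant of them, Cd68 (0.69, q = 0.0933) and Aif1 (-0.10, q = 0.904), differed in sign in the authors' deposited table. With 1 added to each FPKM the microglia median was 0.15 and no longer past the threshold (percentile 95.2). Markers of leptomeninges and choroid plexus had a median of 0.13 (percentile 85.0), or 0.21 and past the threshold with the trend of folds on transcript length and GC removed (percentile 97.9). Here Enpp2 (-0.95), also made by oligodendrocytes, was the member that fell in the authors' deposited table. Genes of striatal medium spiny neurons, which a cortical dissection can carry along, had a median of -0.16 (percentile 0.54). Of 19 members 4 fell, among them Penk (-0.77), Adora2a (-0.66) and Syndig1l (-0.60) in the authors' deposited table. Called-lower striatal markers were not over-represented after adjustment (Fisher's exact test, adjusted p = 0.0608). Hippocampal and thalamic markers lay within the random range (median -0.11, percentile 4.15) with 2 of 19 higher, Pdzd2 (0.74) and Ntng1 (0.49), and 2 lower, Fibcd1 (-0.44) and Lct, in the authors' deposited table.

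**Figure D2:**
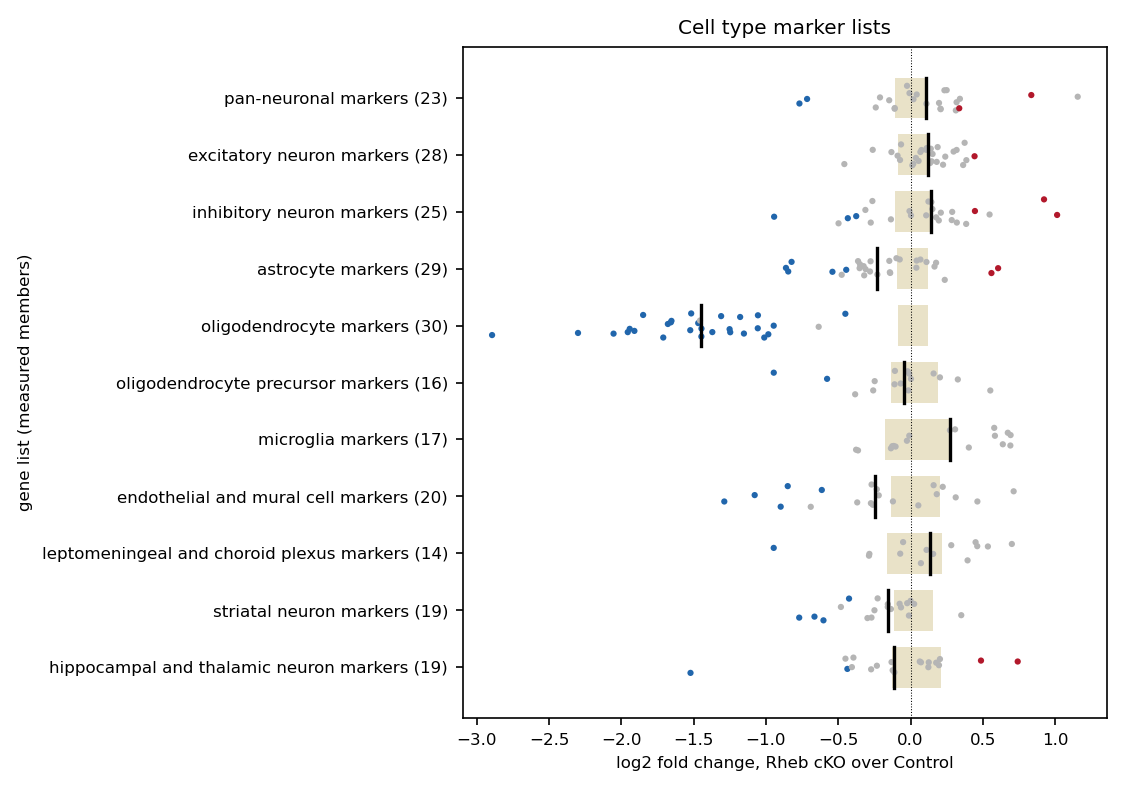
Log2 fold change of Rheb cKO over Control (x axis) for each measured member of the cell type marker lists (rows, number of measured members in brackets); red points are called higher, blue points called lower and grey points not called, with vertical jitter only for legibility. Black bars are list medians and shaded bands the central range of medians of 10000 matched random lists; the oligodendrocyte median of -1.45 lies far to the left of its band, and the microglia median of 0.27 to the right of its own.

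Neuronal markers changed little as a group. Pan-neuronal markers had a median of 0.11 (percentile 96.1, within the random range), excitatory markers 0.12 (percentile 97.3, within it) and inhibitory markers 0.14 (percentile 97.6, just past it). The pan-neuronal median exceeded the pooled median of 111 non-neuronal markers, -0.28, by 0.39 (percentile 100). Oligodendrocyte markers carry much of that gap, since over the other 81 non-neuronal markers it was 0.23 (percentile 99.97). Within these lists a few genes stood out. The neurofilament genes Nefm (-0.77, q = 0.00291) and Nefh (-0.72, q = 0.00161) fell in the authors' deposited table, while Snhg11, a long RNA of neurons, rose (0.84, q = 0.00291), as did Celf4. Snhg11 is also 1 of 13 nuclear or non-polyadenylated RNAs picked after the values were seen, all above 0, so its rise need not be a change of neurons. Crym (0.44, q = 0.00956), a deep-layer marker, was the single excitatory marker of 28 called in the authors' deposited table. Inhibitory markers split. Pvalb (-0.94), the calcium-binding protein of fast-spiking interneurons, fell together with Npy and Sst, whereas Reln (1.01), Htr3a (0.92) and Lhx6 rose, all in the authors' deposited table. Neither direction was over-represented (Fisher's exact test, adjusted p = 0.304 for higher and 0.366 for lower). The call for the inhibitory list is fragile, since its percentile was 95.2 when 1 was added to each FPKM.

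Genes of the mTORC1 pathway did not move as a group. Their median was 0.04 (percentile 53.9), or -0.045 with the trend of folds on transcript length and GC removed (percentile 10.5), and 39 of 43 were not called. Besides Rheb, Sesn2 (-0.68, q = 0.0111), a stress-induced brake on mTORC1, fell in the authors' deposited table. Irs2 (0.91, q = 0.0362), an adaptor of the insulin receptor, rose in the authors' deposited table, and so did Rragb, a GTPase that relays amino acid supply.

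Genes that build cholesterol and unsaturated fatty acids were lower. Of 36 measured, 15 fell (20 when adjusted over the list alone, with 1 higher) and the rest were not called. Their median was -0.42 (percentile 0), and the over-representation was strong (Fisher's exact test, adjusted p = 4.46e-10). Among those that fell in the authors' deposited table were Scd1 (-1.81), a fatty acid desaturase, and Msmo1 (-1.14), an enzyme of late cholesterol synthesis, each with q = 0.00161. Oligodendrocytes express these genes at high levels, and their markers had a median of -1.45 in the same comparison.

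Genes of the translation machinery were slightly higher. Cytosolic ribosomal protein genes had a median of 0.12 over 80 genes (percentile 100), with 9 called higher, 1 lower, and 11 higher when adjusted over the list alone (Fisher's exact test for higher, adjusted p = 0.0436). The median was 0.20 with the trend of folds on transcript length and GC removed. Rpl4 (0.49, q = 0.00291) and Rpl5 (0.44, q = 0.0307) rose in the authors' deposited table. Rpl22l1, the paralog of Rpl22, was the member that fell (-0.40 in the authors' deposited table). A list of translation factors and a few other genes whose mRNA starts with a TOP motif, the sequence through which mTORC1 controls translation, had a median of 0.15 (percentile 99.5), and 6 of 25 rose (adjusted p = 0.00479, Fisher's exact test). Among them were Eif3f (0.50, q = 0.00161) and Eef1a1 (0.48, q = 0.0432), from 1342 to 1875 FPKM in the authors' deposited table. Vim (1.35, q = 0.00161), the filament protein vimentin, was the member with the highest fold in the authors' deposited table and is also on the reactive astrocyte list. Without Vim 5 of 24 rose (Fisher's exact test, adjusted p = 0.0240), and the 15 Eif, Eef and Pabpc members alone had a median of 0.19 (percentile 99.6). Against random lists not matched on expression the full list lay at percentile 96.0, within the range, and with the length and GC trend removed its median was 0.12 (percentile 95.6), also within it. Ribosomal protein genes and Eef1a1 share sequence with many processed pseudogenes, so their values depend on how shared reads were assigned.

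Subunits of oxidative phosphorylation in the nuclear genome were slightly lower, with a median of -0.12 over 76 genes (percentile 0). Of these, 8 fell, both over all genes and when adjusted over the list alone, which was no over-representation after adjustment (Fisher's exact test, adjusted p = 0.111). With the length and GC trend removed the median was -0.066 (percentile 0.01). In the authors' deposited table Cox5a (-0.47), Atp5e (-0.46) and Ndufs5 (-0.43) led, and Cox6b1 fell from 1304 to 1017 FPKM (-0.36, q = 0.0327). Pyruvate dehydrogenase and citric acid cycle genes stayed within the random range (median 0.03, percentile 67.0). Of the 27, 0 were called by Cuffdiff, while 4 were higher and 1 lower at an unadjusted p under 0.05. Mdh2 (0.05, q = 0.890) and Idh3b (0.09, q = 0.868) were the most abundant in the authors' deposited table. Glycolysis and lactate genes had a median of 0.00 (percentile 44.4). Pfkfb3 (-0.99, q = 0.00161), which makes an activator of glycolysis, and Aldoc (-0.44, q = 0.0317), an aldolase of astrocytes, fell in the authors' deposited table. Slc2a3 (0.46, q = 0.00406), the neuronal glucose transporter, rose in the authors' deposited table.

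Stress and lysosome programmes stayed within the random range. Targets of ATF4, a transcription factor that answers amino acid shortage, had a median of -0.04 (percentile 11.0), with 3 of 35 lower and 1, Slc3a2, higher. Those lower in the authors' deposited table were Mthfd2 (-0.92, q = 0.0142), Phgdh (-0.53, q = 0.00161) and Atf4 itself (-0.48, q = 0.00625). Targets of TFEB, the lysosome regulator that mTORC1 restrains, had a median of -0.04 (percentile 6.02), with 6 of 49 lower (Fisher's exact test, adjusted p = 0.111). Sgsh (-0.94), Tfeb (-0.72) and Hexa (-0.71) fell most in the authors' deposited table. Both lists lay past the lower threshold once the trend of folds on transcript length and GC was removed, at percentiles 2.44 and 2.09.

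Genes induced by neuronal activity split in direction, with more lower than higher. Of 38, 9 fell and 4 rose (11 and 5 when adjusted over the list alone). Their median was -0.16 (percentile 0.02), their mean -0.05, and called-lower members were over-represented (Fisher's exact test, adjusted p = 0.000776). The highest folds in the authors' deposited table belonged to the transcription factor Npas4 (1.29), Cyr61 (0.92) and Junb (0.79), each with q = 0.00161. Sik1 (-0.72) and Arc (-0.68), which acts at active synapses, fell in the authors' deposited table; they were picked for naming after their values were seen.

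Synaptic genes were slightly higher. Glutamatergic synapse genes had a median of 0.15 over 40 genes (percentile 99.7), of which Shank2 (0.74, q = 0.00161) and Shank1 (0.49, q = 0.0177), scaffolds of the postsynaptic density, rose in the authors' deposited table. These 2 calls were no over-representation (Fisher's exact test, adjusted p = 0.976). Presynaptic vesicle genes had a median of 0.15 (percentile 99.9). Here 5 of 40 rose, and 10 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.111). Rims2 (0.64) and Sv2c (0.58) led in the authors' deposited table. Neuronal markers had medians close to these, 0.11 for the pan-neuronal, 0.12 for the excitatory and 0.14 for the inhibitory list, and the synaptic lists share members with them, such as Snap25, Syn1, Syt1, Sv2b and Camk2a. Voltage-gated ion channel genes lay within the random range (median 0.09, percentile 89.5), with 3 of 45 higher and 2 lower. Scn4b (-0.93), a sodium channel subunit, fell and Kcnip4 (0.49) rose in the authors' deposited table. Folds rose with transcript length over protein-coding genes (Spearman rho 0.185 across genes, which are not independent replicates). With that trend and the one on GC removed, the glutamatergic list lay at percentile 96.6, within the range, and the ion channel list had a median of 0.0085 (percentile 45.2). Presynaptic genes then had a median of 0.14 (percentile 99.5). Medians of the neuronal markers were then 0.13 for the pan-neuronal, 0.074 for the excitatory and 0.081 for the inhibitory list.

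Genes of reactive astrocytes were higher. The median was 0.32 over the 14 measured of 26 genes (percentile 99.6). Of the 14, 5 rose, or 6 when adjusted over the list alone, and 1 fell (Fisher's exact test for higher, adjusted p = 0.00238). Over the 9 with a mean FPKM of 1 or more the median was 0.27 (percentile 98.6). The complement gene C4b rose from 3.51 to 15.2 FPKM (2.11, q = 0.00161) in the authors' deposited table, with Vim (1.35), Gfap (0.61, q = 0.0189), Cp and Cd44. The member that fell was Sphk1. Genes of activated microglia and the interferon response did not pass the threshold (median -0.14, percentile 2.52, mean 0.18). In that list 2 of 16 rose, the interferon-induced membrane genes Ifitm3 (1.38, q = 0.00161) and Bst2 (1.22, q = 0.00699) in the authors' deposited table.

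**Figure D3:**
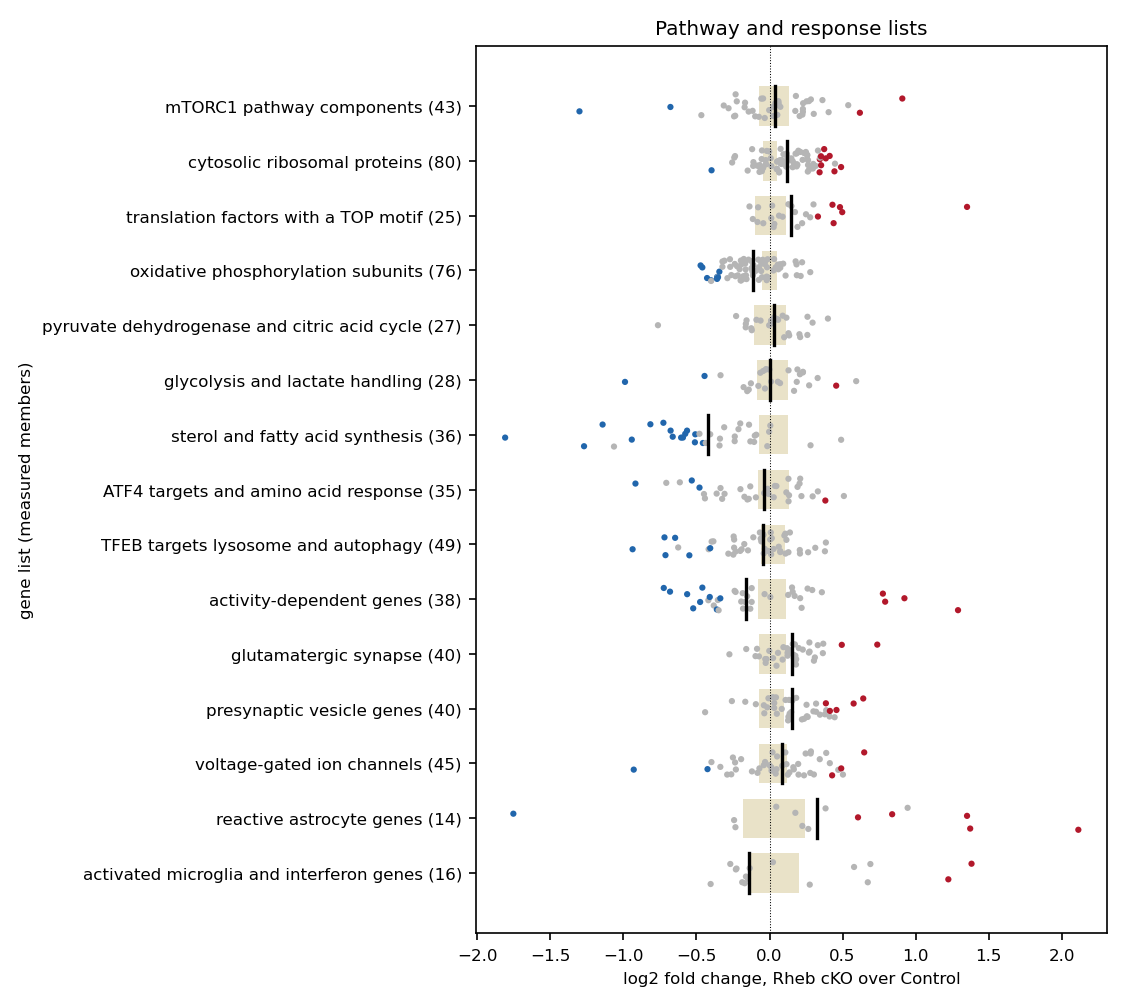
Log2 fold change of Rheb cKO over Control (x axis) for each measured member of the pathway and response lists (rows, number of measured members in brackets), with colours, black median bars and shaded random ranges as in the plot of cell type markers. The sterol and fatty acid median of -0.42 lies left of its range and the reactive astrocyte median of 0.32 right of its range, while the mTORC1 pathway median of 0.04 lies inside.

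Checks on sex and blood showed no called difference by Cuffdiff. The 3 Y-linked genes measured had 0 calls and 0 at an unadjusted p under 0.05, with Eif2s3y at 0.27 (q = 0.933) and Ddx3y at 0.01 (q = 0.997) in the authors' deposited table. The 5 haemoglobin and blood genes also had 0 calls and 0 at an unadjusted p under 0.05, with Hba-a1 at -0.06 (q = 0.929) and Hbb-bs at 0.17 (q = 0.690) in the authors' deposited table.

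Beyond the lists, the highest rise among called genes with a mean FPKM of 1 or more was in Dlk1, a paternally expressed imprinted gene on chromosome 12 (109452823 to 109463336, plus strand). Its FPKM went from 2.24 to 24.8 in the authors' deposited table (log2 fold change 3.47, q = 0.00161). Mkrn3, another paternally expressed imprinted gene, followed at 2.52 (q = 0.00161), from 0.351 to 2.02 FPKM in the authors' deposited table. Glycam1 rose from 0.517 to 2.92 FPKM in the authors' deposited table. Gm26917 (2.38), Tcp11 (2.35), Cdr1 (2.07), Capg (2.03) and Gm21967 (1.92) were also at the upper end in the authors' deposited table, all at FPKM under 10 in both groups. Gm26917 ends on chromosome 17 at 39846341, beside the 18S ribosomal RNA copy Rn18s-rs5 (39846353 to 39848827), which rose from 2307 to 3741 FPKM (0.70, q = 0.0142) in the authors' deposited table.

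Several genes at the lower end are known from myelin and the node of Ranvier. Hapln2, a link protein of the nodal matrix on chromosome 3 (88021750 to 88027583, minus strand), fell by 3.04 on the log2 scale in the authors' deposited table, from 14.6 to 1.78 FPKM. The lipocalin gene Apod fell from 110.5 to 17.6 FPKM (-2.65) and the myelin surface gene Mog from 88.3 to 22.8 FPKM (-1.96) in the authors' deposited table. Galnt6 (-2.07), Itgb4 (-2.33) and a transcript of unknown coding status annotated from 88030878 on the same chromosome as Hapln2 (-2.06) were also among the lowest in the authors' deposited table. Ighm, the immunoglobulin mu heavy chain, fell by 2.81 on the log2 scale, from 18.6 to 2.64 FPKM, in the authors' deposited table.

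In all, 14 of the 28 lists lay past the threshold of random lists, 7 above and 7 below, where 1.4 would be expected by chance, and 7 of the 56 Fisher tests passed after adjustment. Genes of a list are not independent replicates, and without values per library no correlation between them could be estimated, so the percentiles describe these pooled values and not the spread between libraries.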

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

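Removal of the length and GC trend, the reduced lists and the values without oligodendrocyte markers were chosen after the data had been seen; the other settings were fixed beforehand. No paired analysis was possible because the values are pooled over the libraries of each group, and for the same reason neither leaving out a library nor regrouping the libraries was possible, and the limits set by depth per library stay unknown. The counts of called genes moved with the threshold. At a q under 0.01 there were 256 higher and 365 lower genes, at a q under 0.1 there were 826 higher and 811 lower, and with a fold of at least 1.5 there were 251 higher and 393 lower. The share of calls that were higher was 47.5% as reported, 41.2% at the stricter q, 50.5% at the looser q and 39.0% with the fold minimum. With adjustment over genes with a mean FPKM of 1 or more, 519 were higher and 571 lower, and without the called oligodendrocyte markers 576 were lower. Adjustment over all genes with status OK, rows naming a single gene, folds relative to the median fold and the shorter table could not give other counts here, so they test nothing. Rheb had a log2 fold change of -1.21 with 1 added to each FPKM, -1.29 with 0.1 added and -1.33 relative to the median fold. Adjustment over genes with a mean FPKM of 1 or more left all 92 other named genes on their side of the q threshold; adding 1 to each FPKM cannot turn a fold and tests no call.

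Of 149 values for the 28 lists and the neuronal against non-neuronal pair, 134 kept their direction and their side of the threshold. With 1 added to each FPKM, microglia markers (median 0.15) and inhibitory neuron markers (0.11) were no longer past it. With 0.1 added, excitatory neuron markers passed it (0.12, percentile 97.7). Among genes with a mean FPKM of 1 or more, inhibitory markers (0.14) were no longer past it, activated microglia and interferon genes passed it (-0.14, percentile 2.25), and hippocampal and thalamic markers turned from -0.11 to 0.064, within the random range both times. Against random lists not matched on expression, translation factors with a TOP motif (0.15) and inhibitory markers (0.14) were within the range. With the length and GC trend removed, translation factors (0.12), the glutamatergic synapse (0.10) and inhibitory markers (0.081) were no longer past the threshold, ATF4 targets (-0.086), TFEB targets (-0.059) and leptomeningeal and choroid plexus markers (0.21) passed it, and the mTORC1 pathway turned from 0.04 to -0.045, within the range both times. The cause of these shifts was not tested beyond the setting itself. Without Vim the translation factors stayed past the threshold (0.14, percentile 99.3), as did their Eif, Eef and Pabpc members alone (0.19, percentile 99.6). The sterol list was also reduced by members that are oligodendrocyte markers or fell further than the median of those markers. That kept 35 of 36 genes (median -0.41, percentile 0), so it tests little.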

Other observations

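The gene groups described in this part and the tests on them were chosen after values had been seen; the removal of the length and GC trend was chosen after the main results, with its possible outcomes written down before it was run. The RNA-binding proteins Rbm3 and Cirbp, whose mRNAs rise when cells are cooled, stood at 1.44 and 1.07 on the log2 scale in the authors' deposited table (q = 0.00161 each), from 25.5 to 68.9 and from 98.0 to 205.5 FPKM. Of 12 replication-dependent histone genes, 4 fell, with a list median of -0.74 (percentile 0 among matched random lists), and Top2a, a gene of dividing cells, fell by 1.75 on the log2 scale in the authors' deposited table (q = 0.00406). Of 17 genes that glucocorticoids induce, 4 rose, among them Fkbp5 (0.61) and Klf9 (0.70), and 2 fell, Tsc22d3 (-0.52) and Fam107a (-0.41), in the authors' deposited table. The median of these 17 was 0.22, past the threshold (percentile 99.2). Fisher's exact test for called-higher members gave an adjusted p of 0.0193, which is no independent support, as the group was chosen after values were seen. The 13 mRNAs of the mitochondrial genome had a median of 0.12 (percentile 92.8), with mt-Co1 (0.85) higher and mt-Nd3 (-0.46) lower in the authors' deposited table. The lactate transporter genes Slc16a1 (-0.14, q = 0.679), Slc16a7 (-0.08, q = 0.931) and Slc16a3 (0.59, q = 0.0842) were not called in the authors' deposited table. Apoe, an abundant transcript of astrocytes, had 6683 and 6793 FPKM (log2 fold change 0.02, q = 0.961) in the authors' deposited table.

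Mature oligodendrocyte markers had a median of -1.45. Less RNA of every non-neuronal cell type in the Rheb cKO precipitates could lower these types alike or unequally. A Control group without Cre, and hence without tagged neuronal ribosomes, would also bring such a loss. The oligodendrocyte median lay below that of 81 astrocyte, precursor, microglia and endothelial and mural markers by a difference of -1.34 (percentile 0 of random list pairs). That argues against an equal loss in every type as the whole cause of this fall. An unequal loss stays open, and either kind does for the smaller shifts of other lists. The trend on transcript length and GC is also argued against, as the median was -1.48 with it removed (percentile 0). A dissection with less striatum and adjacent white matter stays open, since striatal markers had a median of -0.16 (percentile 0.54). Their called-lower members were not over-represented (Fisher's exact test, adjusted p = 0.0608). The striatal fall was far smaller than -1.45, and it holds no measure of the white matter. An effect of the genotype on oligodendrocytes also stays open and was not tested.

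Sterol and fatty acid synthesis genes were lower by a median of -0.42. The length and GC trend is argued against as the whole cause, since the median with it removed was -0.41 (percentile 0). A smaller share of oligodendrocyte RNA cannot be told apart from lower expression of these genes in neurons, as both cell types express them and the pooled values hold no measure of either alone. Other cell types were not weighed here, though astrocyte markers also had a lower median (-0.23, percentile 0). That the list's median of -0.42 is smaller than the oligodendrocyte fall of -1.45 decides nothing. An effect of Rheb loss on these genes in neurons, which mTORC1 signalling to sterol regulators makes a candidate explanation, was not tested.

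A set of 13 RNAs that are nuclear or lack a poly(A) tail, picked after their values were seen, had a median of 0.84, and 10 of them rose, among them Rnu1a1 (1.76), Rn7sk (1.28), Malat1 (1.12), mt-Rnr2 (0.74) and Rn18s-rs5 (0.70) in the authors' deposited table. Other RNAs of such classes did not all rise, so the uniform direction of the 13 rests on their choice. At a mean FPKM of 1 or more, 2 genes annotated as ribosomal RNA had a median of -0.055. The median was 0.14 for 3 small nuclear RNA genes and -1.04 for 7 microRNA genes. It was 0.62 for 2 mitochondrial ribosomal RNA genes and 2.40 for 5 small nucleolar RNA genes. The 12 histone genes, chosen by symbol, did not follow the 13 (median -0.74). More nuclear RNA of all kinds in the Rheb cKO libraries stays open for part of the rise of the 13. The 195 long intergenic RNA genes outside that group had a median of 0.20 (percentile 100). Of these, 15 were called higher and 4 lower (Fisher's exact test for higher, adjusted p = 0.0635). Their biotype does not say that they are nuclear, and nuclear RNA would not cover the mitochondrial mt-Rnr2. Less complete poly(A) selection cannot be told apart, and the histone median does not decide it. Whether the histone mRNAs counted here lacked the tail is unknown, and the fall of Top2a leaves open that fewer dividing cells lowered them. An effect of genotype on these RNAs was not tested.

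A wider shift of imprinted genes, prompted by Dlk1 and Mkrn3, was tested as a hypothesis on 23 other imprinted protein-coding genes, and their median of 0.15 did not pass the threshold (percentile 95.6), with 3 called higher and 1 lower. A wider shift of genes of fast-spiking parvalbumin interneurons, prompted by Pvalb, Nefm, Nefh and Scn4b, was tested on 21 further genes, whose median of -0.062 did not pass it either (percentile 8.84), with Hapln4 (-0.88) and Sema7a (-0.72) lower in the authors' deposited table. A difference in the time of day at collection was tested on 7 clock genes against 3 of the opposite phase. The 7 alone had a median of 0.29 (percentile 99.5), past the threshold, with 6 of them above 0, and the 3 had a median of 0.12 (percentile 67.2). The medians differed by 0.16 (percentile 78.7), and with so few genes this leaves the time of day open; 0 of the 10 were called by Cuffdiff, and 2 reached an unadjusted p under 0.05.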
